A study of Homo sapiens with 4 samples.

How the data were processed

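RNA was measured by sequencing in 4 libraries of primary HUVECs, 2 transfected with an siRNA against INO80 and 2 with a negative control siRNA, grouped by their labels. Per the labels, total RNA was extracted with a column kit and libraries were made with a NEBNext Ultra RNA kit. The deposited files hold, for each library, whole-number counts of reads per gene, not normalized by the authors. Per the submitters' processing notes the genome build was GRCh37 and DESeq2 was used. The aligner, the counting program, the strand setting and their versions are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner may not be told apart. Gene IDs in the files carry the suffix of an annotation mapped to GRCh37. The reference at hand is GRCh38, so no coordinates are given. Its GENCODE release 29 annotation was used for gene type, and for length and GC content of a gene's longest transcript. It also gave the chromosome used to leave out Y-linked genes, and gene names used beside current symbols to match rows and list members.

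The files held 60829 gene rows, of which 56807 matched a gene symbol by ID. Rows for unmapped, multimapping, no-feature and ambiguous reads were kept out of library sizes and tests. In siINO80 replicates 1 and 2, unmapped reads were 7.37% and 7.75% of all, no-feature reads 4.73% and 4.17%, and ambiguous reads 8.50% and 8.49%. In control replicates 1 and 2 they were 6.78% and 8.61%, 3.53% and 3.32%, and 9.10% and 8.91%. The multimapping row is 0 in each file, and how multimapping reads were treated is not given in the sources used here, so genes with near-identical copies are uncertain. Reads in genes totalled 26456811 and 37344989 in the siINO80 libraries and 44316554 and 42491341 in the control libraries.

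Genes were kept by edgeR's filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels in CPM use the TMM-scaled library size. The SE of a log2 fold change is its size divided by the square root of the F statistic. The fit has 2 residual degrees of freedom per gene and borrows 17.9 from other genes. An exact test on 2 against 2 libraries cannot give a p below 0.333, so calls rest on that borrowed spread.

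Gene lists (33 lists, 981 members, 976 matched) were written from textbook knowledge before the data were examined: INO80 complex subunits, other chromatin remodellers and H2A.Z, DNA replication and E2F targets, G2/M and mitosis, replication-dependent histones, p53 targets, double-strand break repair, interferon-stimulated genes, NF-kB and inflammatory genes, endothelial identity, arterial and Notch, venous and lymphatic, sprouting and tip cells, shear-responsive genes, endothelial-mesenchymal transition and TGF-beta, extracellular matrix, YAP and TAZ targets, oxidative phosphorylation, mitochondrially encoded mRNAs, glycolysis and hypoxia, cholesterol biosynthesis, ATF4 and amino acid response, endoplasmic reticulum chaperones, cytosolic heat shock, ribosomal proteins, ribosome biogenesis and MYC targets, immediate early genes, autophagy and lysosome, and markers of smooth muscle cells and pericytes, fibroblasts, leukocytes, epithelial cells and erythroid cells. Some genes are in more than 1 list. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the lists, with camera's estimated correlation and fry beside it. The 3 lists chosen after seeing the data (MHC class I antigen presentation, NRF2 targets, and fatty acid uptake and PPAR targets) were adjusted together with the 32 fixed lists tested.

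The genes named were set by a rule written before the data were examined. It takes INO80. Among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM in one group and both siINO80 libraries on the same side of both controls, it takes the 10 largest increases, the 10 largest decreases and the 3 smallest p in each direction. It also takes up to 4 members of each list with the smallest p. XIST and Y-linked genes were left out. Not every gene the rule takes is described, and the values of some genes are not reported here.

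The procedure was tested on simulated data with the comparison's own library sizes, levels and dispersions. Of the 16421 genes simulated, 16113 passed the filter, 198 of the 200 changed ones among them. It recovered 57.6% of 66 genes changed 1.2-fold, 71.6% of 67 changed 1.5-fold and 87.7% of 65 changed 2-fold, with 13 unchanged genes among 156 calls. In a second simulation of 32 lists of 30 genes, the 1 list lowered to 0.8 of its level was called and 0 of the others. Those genes did not depend on each other, unlike real ones. Only 200 genes were changed in the first simulation and 1 list in the second, where the data gave 10109 genes and 12 lists called. The recovered shares and the list result therefore need not carry over to these data.

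Alternatives were RLE, upper-quartile and no scaling, other filters, DESeq2 1.42.0, limma-voom, robust edgeR, a test against a fold of 1.2 (glmTreat), thinning to the smallest library, GC correction, a replicate block with and without it, leaving out each library, and the other list tests. A length correction and TMM without interferon and MHC class I genes were chosen after seeing the data. Other strand columns, planned as an alternative, could not be tried, since each file holds 1 count column. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.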

Results

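RNA sequencing was used to profile human umbilical vein endothelial cells (HUVECs), primary cells from the lining of the umbilical vein, after transfection with an siRNA against INO80 or with a negative control siRNA. INO80 is the ATPase of a chromatin remodelling complex that moves nucleosomes and acts on the histone variant H2A.Z. The series holds 4 libraries, 2 per group, and the comparison asks which transcripts differ between cells given the 2 siRNAs. Each siRNA was used in a single group and they came from different suppliers, so loss of INO80 cannot be told apart from the reagent. The siINO80 libraries held 26456811 and 37344989 reads in genes, and the control libraries 44316554 and 42491341. The labels name replicates but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. If it is, a difference between cultures cannot be told apart from the siRNA either. That spread was small, with a common biological coefficient of variation of 2.33%. Counts of replicate pairs still differed by more than sampling noise: among genes with at least 100 counts over the pair, 12.1% of 12120 in the siINO80 pair and 13.9% of 12546 in the control pair had a chi-square p below the level at which sampling alone would give 5%. Levels are given as CPM (counts scaled to a common library total), mean ± SD of 2 libraries per group.

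INO80 mRNA (ENSG00000128908.16_4) fell from 64.8 ± 3.71 CPM in control cells to 30.04 ± 0.886 CPM in siINO80 cells, which left 46.5% of the control level. Its counts were 785 and 1152 in the siINO80 libraries against 2958 and 2623 in the control libraries. The log2 fold change was −1.11 (SE 0.047, edgeR quasi-likelihood test, adjusted p = 1.46e-14). Of 15 INO80 complex subunits tested, 5 rose (NFRKB, RUVBL2, INO80D, TFPT and INO80E) and 4 fell (INO80, ACTB, MCRS1 and ACTR8). The same counts held when adjusted over the list alone. NFRKB, a subunit that regulates the complex's activity, rose from 48.0 ± 0.463 to 78.5 ± 1.03 CPM, the largest increase among them, and the list as a whole was not called (median log2 fold change 0.04, camera adjusted p = 0.968). INO80D, TFPT, INO80E, MCRS1 and ACTR8 are named here because their counts were few, after their values were seen, as are other genes named below only as the members behind a count of 5 or fewer. Among 32 other remodellers and H2A.Z genes, 11 rose and 12 fell (12 and 12 adjusted over the list alone; camera adjusted p = 0.943). ARID1B, of the BAF complex, rose by 0.62 on the log2 scale and CHD3, of the NuRD complex, fell by 0.40.

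**Figure D1:**
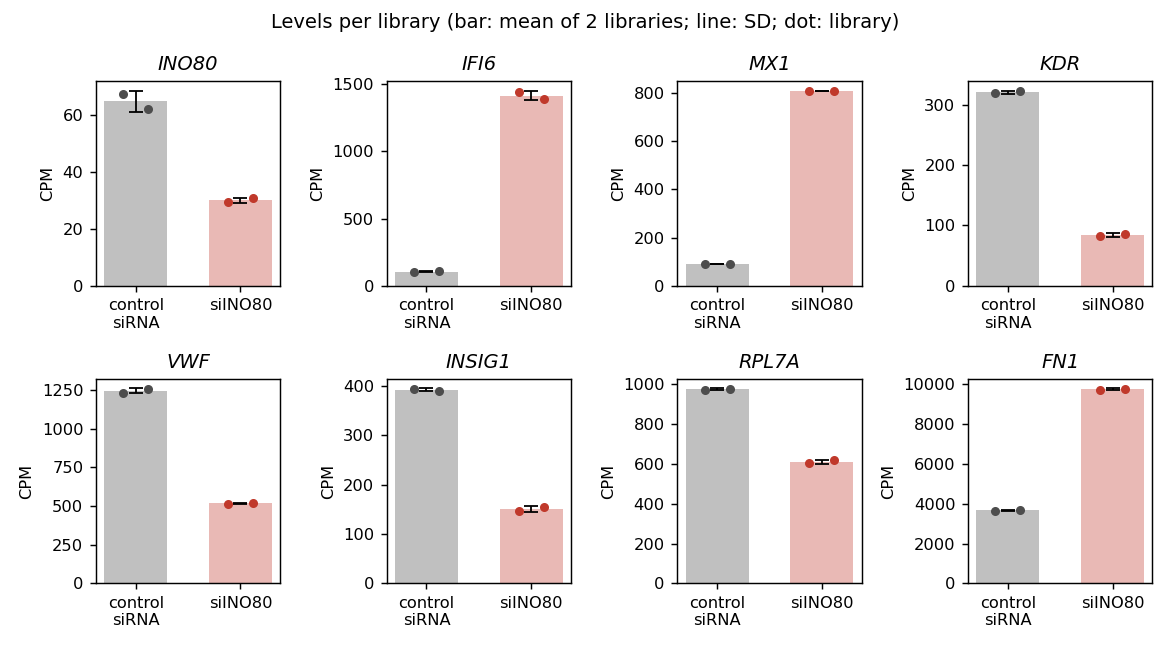
CPM of 8 genes in control siRNA (grey) and siINO80 (red) libraries, on linear axes that start at 0. Bars are means of 2 libraries, black lines the SD and dots single libraries; both siINO80 libraries lie on one side of both control libraries for each of these genes, as for INO80 at 30.04 against 64.8 CPM.

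Of 16421 genes tested, 10109 (61.6%) differed between the groups, 5121 higher and 4988 lower in siINO80 cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small, with a median of 1.35-fold among the genes called. Changes over 2-fold numbered 1067 increases and 720 decreases, and over 4-fold 241 and 140. The 2 libraries of one group lay apart from both of the other in 13056 genes, or 79.5%, where chance gives 33.3%. Tested against a fold of 1.2 in place of no change, 5500 genes were called, 2855 higher and 2645 lower. The groups of genes described next were written as lists before the data were examined. Of 33 lists, 32 had enough tested members for camera with a preset correlation, and 12 were called, 3 higher and 9 lower. With an estimated correlation none of the 12 was called, and the smallest adjusted p was 0.194. That form takes its p from the 2 residual degrees of freedom, which keeps p-values large. Among the 12 lists the estimate ran from −0.0355 (cholesterol biosynthesis) to 0.417 (interferon-stimulated genes), against the preset 0.01. For cholesterol biosynthesis the unadjusted camera p still went from 5.35e-20 to 0.00931. A call lost in this form therefore does not show that correlation between genes undoes it. The self-contained test fry, which asks only whether a list moves one way on balance, called 23.

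**Figure D2:**
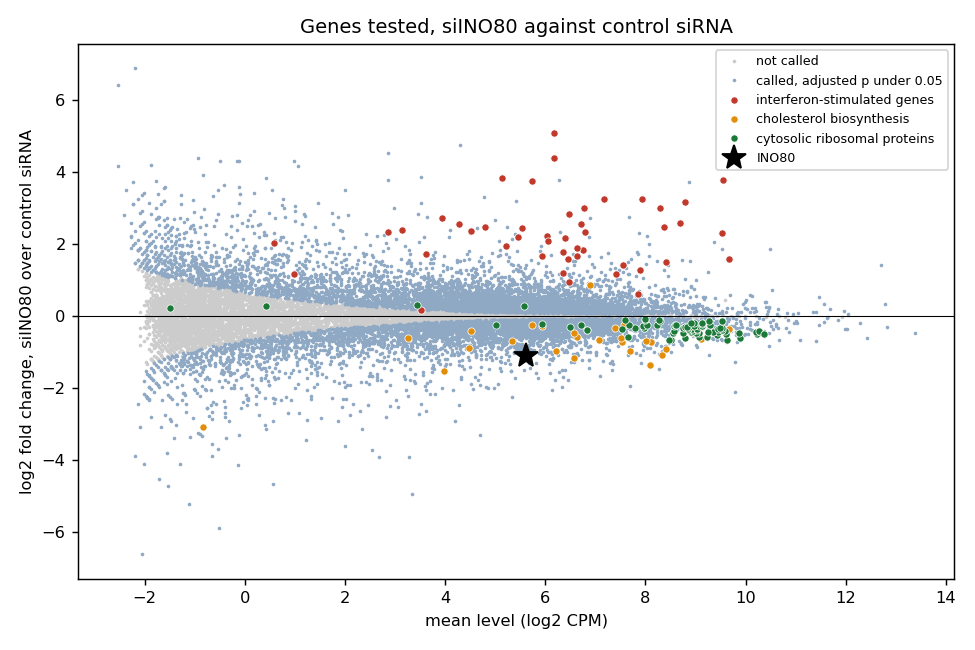
Log2 fold change of siINO80 over control siRNA against mean level (log2 CPM), one dot per tested gene, with Y-linked genes and XIST left out. The interferon-stimulated genes lie above 0, with MX2 highest at 5.08, while most cholesterol biosynthesis and ribosomal protein genes lie below 0 and INO80 is at −1.11.

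Interferon-stimulated genes rose in siINO80 cells: 45 of the 46 tested were higher and none was lower, with the same counts adjusted over the list alone. The exception was IRF1, at 10.9 and 12.2 CPM (edgeR adjusted p = 0.1). The median log2 fold change was 2.27 (camera adjusted p = 1.89e-149, and adjusted p = 0.194 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein, rose from 104 ± 3.51 to 1416 ± 35.8 CPM, and MX1, a GTPase that blocks viral replication, from 90.0 ± 1.91 to 808 ± 0.448 CPM. OAS2, which makes the oligoadenylates that activate RNase L, rose 8.01-fold, and ISG15, a ubiquitin-like modifier, 9.53-fold. MX2 had the largest increase under the selection rule, from 4.38 ± 0.171 to 148 ± 3.50 CPM (log2 fold change 5.08, SE 0.051, edgeR adjusted p = 4.57e-25). The other 9 genes with the largest increases were LGALS3BP (26.9-fold), CCL5 (23.1-fold), IFITM1 (20.998-fold), SECTM1 (14.5-fold), CMPK2 (14.3-fold), LGALS9 (13.7-fold), IFI6 (13.7-fold), TYMP (13.6-fold) and RSAD2 (13.4-fold). IFITM1, CMPK2, IFI6 and RSAD2 are members of the list, and CCL5 encodes a chemokine that attracts T cells. HLA-B, which presents peptides to cytotoxic T cells, rose from 67.0 ± 3.84 to 884 ± 13.7 CPM (13.2-fold), although near-identical HLA genes can share reads and its level is uncertain to that extent. The 2 siRNAs came from different suppliers, one in each group. Of 18 leukocyte markers, 5 were detected well enough to test; CORO1A, ITGAX and LCP1 rose, each to under 3 CPM and also adjusted over the list alone, and the list was not called (camera adjusted p = 0.624).

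Genes that mark endothelial cells fell in siINO80 cells: of 32 tested, 22 were lower, 6 higher and 4 not called, also when adjusted over the list alone. The median log2 fold change was −0.29 (camera adjusted p = 2.71e-10, and adjusted p = 0.194 with an estimated correlation). KDR, the main VEGF receptor, fell from 321 ± 2.35 to 83.7 ± 2.94 CPM (log2 fold change −1.93, SE 0.028, edgeR adjusted p = 1.78e-22). VWF, the adhesive protein stored in Weibel-Palade bodies, fell from 1243 ± 15.8 to 517 ± 5.44 CPM. EMCN, a sialomucin of the endothelial surface, fell to 25.3% of control and CLDN5, a tight junction protein, to 30.8%. CDH5, which encodes VE-cadherin, was among those not called (log2 fold change −0.02).

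Among arterial and Notch genes, 14 of 23 fell and 5 rose, also adjusted over the list alone (median −0.36, camera adjusted p = 0.0114, and adjusted p = 0.597 with an estimated correlation). The retinaldehyde dehydrogenase gene ALDH1A1 fell from 339 ± 2.28 to 136 ± 5.79 CPM, SOX17, a transcription factor of arterial cells, from 56.4 ± 5.79 to 19.6 ± 1.21 CPM, and the Notch ligand gene JAG2 from 97.8 ± 0.532 to 59.9 ± 2.77 CPM. The 5 that rose were HES4, FOXC2, BMX, DLL1 and CXCR4, and HES4, a transcriptional repressor, rose 3.21-fold. Sprouting and tip cell genes fell on balance, 17 of 29 lower and 9 higher, also adjusted over the list alone (median −0.23, camera adjusted p = 0.00815, and adjusted p = 0.482 with an estimated correlation). KDR counts here too, with FSCN1, an actin-bundling protein of filopodia (−0.81 on the log2 scale), and MMP14, a membrane-bound protease (−0.67), while ITGA5, a fibronectin receptor subunit, rose (0.52). Under a filter of 10 CPM on average neither list was called: the median of arterial and Notch genes was then −0.09 (camera adjusted p = 0.189) and that of sprouting and tip cell genes −0.22 (0.0898). Venous and lymphatic genes moved both ways, 5 higher and 7 lower of 14, with the same counts adjusted over the list alone (camera adjusted p = 0.488). LYVE1, a hyaluronan receptor, fell 4.76-fold and NR2F2, a transcription factor of venous identity, rose 1.49-fold. The others that rose were TFPI2, RELN, NR2F1 and ACKR1.

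Cholesterol biosynthesis genes fell, 26 of 27 lower, also adjusted over the list alone, and only STARD4, a sterol carrier, was higher. The median log2 fold change was −0.66 (camera adjusted p = 8.56e-19, and adjusted p = 0.194 with an estimated correlation). INSIG1, which holds the sterol-sensing complex in the endoplasmic reticulum, fell from 391.9 ± 2.99 to 151 ± 6.43 CPM. FDFT1, squalene synthase, fell to 52.6% of control and HMGCS1, the synthase of HMG-CoA, to 50.6%. Endoplasmic reticulum chaperone genes fell as well, 21 of 23 lower and none higher, also adjusted over the list alone (median −0.37, camera adjusted p = 7.63e-08, and adjusted p = 0.194 with an estimated correlation). HSPA5, the main chaperone of that compartment, fell from 1994 ± 21.9 to 1256 ± 24.8 CPM and DNAJC3, its co-chaperone, from 262 ± 0.354 to 143 ± 1.37 CPM, and PDIA4 and HSP90B1 fell by 0.56 and 0.37 on the log2 scale. Of 77 cytosolic ribosomal protein genes, 73 fell and 2, RPL22 and RPL17, rose, also adjusted over the list alone. The median log2 fold change was −0.34 (camera adjusted p = 2.26e-18, and adjusted p = 0.48 with an estimated correlation). RPL7A fell from 976 ± 3.82 to 611 ± 9.23 CPM, RPL13A to 65.5% of control, RPS20 to 65.6% and RPL21 to 62.8%. Ribosomal protein genes have many near-identical pseudogenes with which reads can be shared, so single levels among them are uncertain.

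NF-kB and inflammatory genes fell, 18 of 27 lower and 5 higher (18 and 6 adjusted over the list alone), with a median log2 fold change of −0.73 (camera adjusted p = 0.000118, and adjusted p = 0.265 with an estimated correlation). SELE, the leukocyte adhesion receptor E-selectin, had the largest decrease under the selection rule, from 17.4 ± 0.1202 to 0.517 ± 0.360 CPM (log2 fold change −4.95, SE 0.167, edgeR adjusted p = 3.36e-16), and rested on 7 and 29 counts in the siINO80 libraries. CCL2, a monocyte chemokine, fell from 35.3 ± 1.13 to 8.52 ± 0.976 CPM, and the neutrophil chemokines CXCL1 and CXCL8 fell to 55.1% and 56.7% of control. The 5 that rose were TNFAIP3, ICAM2, PTX3, CSF3 and NFKB1. After SELE, the largest decreases were those of the fatty acid carrier FABP4 (15.1-fold), the aryl hydrocarbon receptor target CYP1A1 (15.02-fold), the matrix protein POSTN (13.1-fold), SESN3 (12.3-fold), COLEC12 (9.93-fold), KLRG1 (8.81-fold), FBXL13 (7.52-fold), the semaphorin SEMA3G (7.52-fold) and C2CD4B (7.04-fold). MMP1, interstitial collagenase, had the smallest p among the decreases and fell from 1428 ± 27.5 to 333 ± 8.41 CPM.

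Genes of G2/M and mitosis rose on balance, 26 of 40 higher and 6 lower, also adjusted over the list alone (median 0.16, camera adjusted p = 0.0113, and adjusted p = 0.496 with an estimated correlation). The kinesins CENPE and KIF11 rose 2.11-fold and 1.81-fold, ASPM, a spindle pole protein, 1.53-fold and KIF20A 1.48-fold. DNA replication and E2F target genes went both ways, 21 higher and 15 lower of 48 (21 and 16 adjusted over the list alone; camera adjusted p = 0.451); CHAF1A, a histone chaperone subunit, rose 1.59-fold and MCM3, of the replicative helicase, 1.36-fold. p53 target genes fell on balance, 18 of 32 lower and 8 higher (19 and 8 adjusted over the list alone; median −0.15, camera adjusted p = 0.0178, and adjusted p = 0.418 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, fell from 334 ± 6.13 to 212 ± 1.01 CPM, and TNFRSF10B, a death receptor, from 453 ± 1.31 to 290 ± 1.22 CPM. CCNG1 and BTG2 fell to 65.6% and 55.6% of control. Under the filter of 10 CPM on average the p53 list was not called (camera adjusted p = 0.0509). Double-strand break repair genes were not called as a list (camera adjusted p = 0.413), with 16 of 35 higher and 7 lower, also adjusted over the list alone. RBBP8, which starts end resection, fell to 51.3% of control and BRCA2, which acts in homologous recombination, rose 1.66-fold. Replication-dependent histones were at the low end of the range measured, and of 17 tested only H2BC5 rose and only H2AC11 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.989). Leaving out single libraries ended those calls: H2BC5 was not called when any one of the 4 libraries was left out (edgeR adjusted p = 0.217 without siINO80 replicate 1, 0.0512 without siINO80 replicate 2, 0.0853 without control replicate 1 and 0.0664 without control replicate 2). H2AC11 was not called without siINO80 replicate 2 (edgeR adjusted p = 0.312) or control replicate 1 (edgeR adjusted p = 0.0595). With DESeq2 neither was called (DESeq2 adjusted p = 0.174 for H2BC5 and 0.128 for H2AC11). H2BC21 (edgeR adjusted p = 0.0642) was called higher with a filter of 1 CPM in 2 samples (0.0405), a GC correction (0.0433) and without siINO80 replicate 2 (0.0439).

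Genes of the endothelial-mesenchymal transition and TGF-beta signalling were higher on balance, 17 of 30 higher and 9 lower, also adjusted over the list alone (median 0.24, camera adjusted p = 0.0197, and adjusted p = 0.418 with an estimated correlation). FN1, fibronectin, rose from 3673 ± 19.5 to 9747 ± 36.4 CPM, TAGLN, an actin-binding protein of contractile cells, from 9.05 ± 0.0618 to 82.3 ± 0.0728 CPM, and the growth factor TGFB2 from 15.7 ± 0.0906 to 69.2 ± 4.21 CPM. BMP4 fell from 203 ± 0.202 to 94.97 ± 1.52 CPM, and the largest change in the list was the 13.1-fold fall of POSTN. Over 2-fold, 5 members rose and 5 fell. The list was not called without control replicate 1 (camera adjusted p = 0.0696) or control replicate 2 (camera adjusted p = 0.129), nor with limma-voom (0.0626), robust edgeR (0.0709), a GC correction (0.063) or a filter of 1 CPM in 2 samples (0.0628). With the filter of 10 CPM on average its median was 0.49 (camera adjusted p = 0.00372). Matrix and basement membrane genes were not called (camera adjusted p = 0.0667), with 18 of 31 higher and 9 lower, also adjusted over the list alone. They were called higher with library totals (camera adjusted p = 0.0468), no filter (0.0139) and without siINO80 replicate 2 (0.0448). COL8A1, a short-chain collagen of vessel walls, rose 2.32-fold and NID1, a basement membrane linker, 2.93-fold, while THBS1, a matricellular inhibitor of angiogenesis, fell to 71.6% of control. Of 6 smooth muscle and pericyte markers tested, TAGLN, SMTN and CNN1 rose and RGS5 fell from 319 ± 5.83 to 149 ± 2.60 CPM, also adjusted over the list alone (camera adjusted p = 0.394), and CNN1 rested on 11 and 12 against 3 and 1 counts. Of 6 fibroblast markers, COL1A2 rose 1.81-fold and COL3A1, COL1A1 and PDGFRA fell, each to a level near 1 CPM or below, also adjusted over the list alone (camera adjusted p = 0.822). PDGFRA was not called without siINO80 replicate 1 (edgeR adjusted p = 0.0623) or with DESeq2 (DESeq2 adjusted p = 0.0642).

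**Figure D3:**
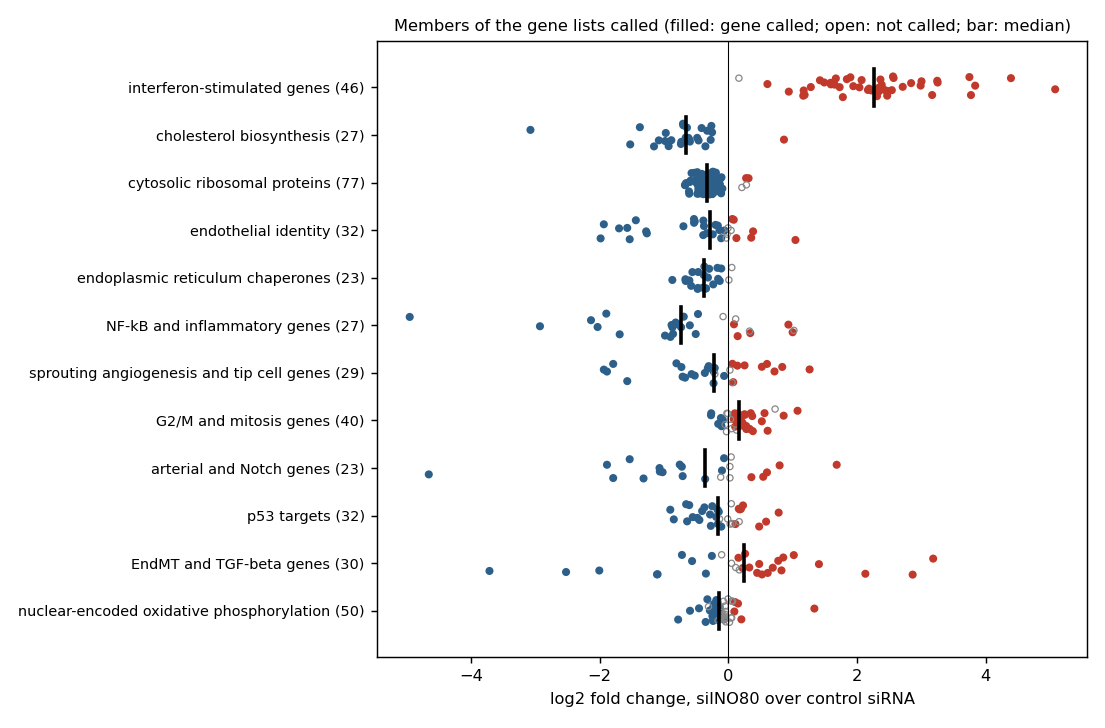
Log2 fold change of siINO80 over control siRNA for the tested members of the 12 lists called by camera with a preset correlation, with the number tested in parentheses and EndMT for endothelial-mesenchymal transition. Filled dots are genes called higher (red) or lower (blue), open dots genes not called and black bars list medians, from 2.27 for interferon-stimulated genes to −0.73 for NF-kB and inflammatory genes.

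Nuclear-encoded genes of oxidative phosphorylation fell slightly, 26 of 50 lower and 5 higher (29 and 5 adjusted over the list alone; median −0.14, camera adjusted p = 0.0416, and adjusted p = 0.687 with an estimated correlation). SDHC, a subunit of succinate dehydrogenase, fell to 58.2% of control and NDUFB5, of complex I, to 66.2%, and NDUFA10, NDUFV2, NDUFA1, COX7B and COX6C rose. That call was not made with RLE (camera adjusted p = 0.055) or upper-quartile (0.0501) normalization or library totals (0.0813), the filter of 10 CPM (0.107), DESeq2 (0.068), thinning (0.0616) or a length correction (0.23), among the fits without a replicate block. Of 13 mitochondrially encoded mRNAs, 7 fell and 3 (MT-ND2, MT-ND5 and MT-ND1) rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.105), and MT-CO3, a subunit of cytochrome oxidase, fell to 61.6% of control. This list was called lower with DESeq2 (camera adjusted p = 0.00618), limma-voom (0.0461), no filter on low counts (0.0155) and without siINO80 replicate 2 (0.0393), and its median was 0.0408 with a length correction. Ribosome biogenesis and MYC target genes were not called (camera adjusted p = 0.0921), with 20 of 33 higher and 5 lower (20 and 6 adjusted over the list alone). They were called higher with limma-voom (camera adjusted p = 0.0229), robust edgeR (0.0338), no filter (0.0342), a GC correction (0.0422) and without control replicate 2 (0.0456). POLR1A, the largest subunit of RNA polymerase I, rose 2.16-fold, and ODC1, NPM1, NHP2, GAR1 and DKC1 fell. Genes of the ATF4 and amino acid response were 9 higher and 14 lower of 29 (10 and 14 adjusted over the list alone; camera adjusted p = 0.202, and 0.0379, lower, without a filter), and SLC7A11, the cystine transporter, fell to 36.3% of control. Immediate early genes were 12 higher and 6 lower of 27 (12 and 8 adjusted over the list alone; camera adjusted p = 0.228), with EGR1 rising from 2.99 ± 0.0324 to 21.2 ± 1.95 CPM.

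The remaining lists moved both ways and were not called. YAP and TAZ targets were 9 higher and 8 lower of 21, also adjusted over the list alone (camera adjusted p = 0.639), with CRIM1 down to 56.1% of control. Shear-responsive genes were 5 higher (HMOX1, PTGS1, THBD, KLF6 and KLF10) and 7 lower of 17, also adjusted over the list alone (camera adjusted p = 0.943). HMOX1, heme oxygenase, rose 3.22-fold, and the largest change in the list was the 15.02-fold fall of CYP1A1. Glycolysis and hypoxia genes were 11 higher and 11 lower of 33, also adjusted over the list alone (camera adjusted p = 0.932), with SLC2A3, a glucose transporter, down to 57.0% of control and PFKFB3, an activator of glycolysis, up 1.56-fold. Autophagy and lysosome genes were 14 higher and 9 lower of 30, also adjusted over the list alone (camera adjusted p = 0.932), and LAMP2, a lysosomal membrane protein, rose 2.04-fold. Cytosolic heat shock genes were 10 higher and 7 lower of 20 (11 and 7 adjusted over the list alone; camera adjusted p = 0.989), with DNAJB4 down to 42.9% of control. Of 7 epithelial markers tested, 2 rose, CLDN7 and MUC1, and 3 fell, KRT18 and KRT19 among them, also adjusted over the list alone (camera adjusted p = 0.932). Of the erythroid markers only TFRC, the transferrin receptor of dividing cells, could be tested, and it fell to 78.6% of control. Camera's direction, the median and the mean differed in sign for 4 of the lists not called, namely glycolysis and hypoxia, epithelial markers, shear-responsive genes and histones.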

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

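The comparison described here was chosen after its values were seen. Reads assigned to no feature enter no comparison of the report. In siINO80 cells they took a mean of 4.45% ± 0.4 (SD of 2 libraries) of all reads, against 3.43% ± 0.153 in control cells. Both siINO80 libraries lay above both control libraries, which is what drew attention to the value. A two-sided exact permutation test gave p = 0.333, the smallest that 2 libraries against 2 can give.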

How the results depend on the processing

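The length correction, TMM without interferon and MHC class I genes, and the split by level after thinning were chosen after seeing the data. INO80 was lower and called in each alternative fitted, from −1.05 to −1.18 on the log2 scale. Counts of genes called lay between 7191 (filter of 10 CPM, fewer genes tested) and 10486, apart from the test against a fold of 1.2, which by construction called fewer: 5500, of them 2855 higher and 2645 lower. DESeq2 called 7880. Leaving out single libraries gave 9017 to 9588, with the lone library assumed to vary like the other group. The replicate block gave 10486 calls, and 10444 with the GC correction; the deviations of same-numbered libraries correlated at 0.0545 over genes, and with 2 pairs the numbers are not taken to pair the samples. With the block mitochondrial mRNAs were called lower (camera adjusted p = 0.0429), and with block and GC correction oxidative phosphorylation genes were not called (0.0779); H2BC21 was called higher with the block (edgeR adjusted p = 0.0339) and with both (0.0217). After thinning 15495 genes were tested and 9471 called. Among the 4105 genes with the lowest levels 30.9% of calls were lost, against 2.64% among the 4106 with the highest. Of those lowest genes 927 no longer passed the filter, and any calls among them count as lost. Depth thus limits low genes most, perhaps in part through the filter. Other strand columns were not run, and lists were not tested with glmTreat. Against a fold of 1.2, ACTB, H2BC5, MT-CO2, DNAJA1, SMTN and KRT18 were not called (glmTreat in edgeR, adjusted p from 0.0859 to 1). Lists called went from 12 to 0 with an estimated correlation, the same camera test on 2 residual degrees of freedom. They went to 23 with fry, which asks a different question, and otherwise lay between 8 and 16. Over 2848 values of named genes in the alternatives, 16 lost their call, 5 gained one and 0 changed sign. Over 661 values of lists, 29 lost their call, 12 of them with the estimated correlation, and 25 gained one.

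In 50 list values, camera's or fry's direction or the sign of the median turned. They belong to 10 lists not called in the main analysis or there (smallest adjusted p 0.105 and 0.175), and the cause was not tested. Their median log2 fold changes follow. Heat shock genes had 0.097 with RLE, 0.0898 with upper-quartile scaling, 0.1048 without a filter, 0.0941 thinned, 0.0984 with the replicate block, 0.1117 with block and GC correction, 0.1031 with fry and 0.0992 with length correction, and 0.0584 to 0.1029 leaving out libraries. YAP and TAZ targets had −0.0055 with RLE, −0.0125 with upper-quartile scaling, −0.0054 with DESeq2 and −0.0475 with length correction, and −0.0118 to −0.0035 leaving out libraries. INO80 subunits had 0.0284 without a filter, 0.0314 with DESeq2, 0.0378 with the block and 0.0593 with block and GC correction, and −0.0051 to 0.0389 leaving out libraries. Histones had 0.1989 without a filter, 0.163 with 1 CPM in 2 samples, 0.0826 with limma-voom, −0.1745 thinned, 0.0484 with block and GC correction, 0.0709 with GC correction, 0.0802 with fry and 0.0973 with length correction, and −0.219 to 0.2771 leaving out libraries. Shear-responsive genes had −0.0676 with DESeq2, −0.072 with limma-voom, −0.0672 with robust edgeR and −0.0604 with the block, and −0.0911 to −0.0079 leaving out libraries. Glycolysis genes had −0.02 with the GC correction, also with the block, and −0.0015 to 0.0171 leaving out libraries. Epithelial markers had 0.0062 with library totals, and −0.0886 to 0.0224 leaving out libraries. Other remodellers had −0.0396 with length correction, and −0.0168 to 0.049 leaving out libraries. Smooth muscle markers had −0.0889 without a filter, and mitochondrial mRNAs 0.0408 with length correction.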

Other observations

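The lists in the next 2 paragraphs, and the tests of leukocytes, of the transfected RNA, of smooth muscle cells or fibroblasts, and of transcript length were chosen after seeing the data. The lists were picked after members had been seen to move, so their tests are not independent evidence, and their p-values are adjusted over these 3 lists and the 32 fixed ones together. Of 15 genes of MHC class I antigen presentation, 14 were higher in siINO80 cells, and ERAP1, a peptide-trimming enzyme, was the 1 that fell. The median log2 fold change was 1.87 (camera adjusted p = 4.2e-38, and adjusted p = 0.191 with an estimated correlation). HLA-C rose from 258 to 1077 CPM, with the reads that HLA genes share left open. B2M, the common light chain, rose 3.66-fold, the peptide transporter TAP1 3.57-fold, the immunoproteasome subunit PSMB9 9.90-fold and NLRC5, a regulator of class I genes, 4.20-fold.

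Of 19 NRF2 target genes, 16 were lower, and TXN and HMOX1 were the 2 that rose (median −0.54, camera adjusted p = 1.19e-06, and adjusted p = 0.191 with an estimated correlation). TXNRD1, thioredoxin reductase, fell from 1126 to 682 CPM, OSGIN1 from 31.2 to 11.6 CPM and PIR from 96.2 to 43.0 CPM, while HMOX1 rose from 34.0 to 110 CPM. Genes of fatty acid uptake and PPAR targets were not called as a list (5 of 15 higher, 8 lower, camera adjusted p = 0.917), and their median (−0.14) and mean (−0.88) differ in sign from camera's direction. Among them CD36, a fatty acid receptor of endothelium, had 1 count in siINO80 cells against 96 in control cells, 71.7-fold lower with a 95% counting interval from 12.6 to 2860, and FABP4 fell from 10.7 to 0.702 CPM. ANGPTL4, an inhibitor of lipoprotein lipase, rose 2.40-fold.

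Interferon-stimulated genes were higher in siINO80 cells, 45 of 46. Leukocytes in those cultures would bring their own abundant transcripts, and the median of 18 leukocyte markers was 0.0293 CPM, against 0.0116 CPM in control cells. PTPRC, CD3D, TYROBP and CD52 were at 0 counts, although CORO1A, ITGAX and LCP1 rose. After thinning to the smallest library, 45 of 46 were still called higher. Levels were already scaled to library totals, so thinning could hardly have undone rises of this size and is weak evidence on the shallower siINO80 libraries. A response to the transfected RNA cannot be told apart from the loss of INO80, since each siRNA is in 1 group only and the 2 come from different suppliers; IFNB1 had 10 counts in siINO80 libraries against 1 in controls (13.4-fold, 95% counting interval 1.91 to 581), which either may give. The same confounding holds for the other gene groups, and a difference between cultures stays open too, since replicates may not be separate cultures. An effect of INO80 loss on interferon-stimulated genes thus stays a hypothesis that a second INO80 siRNA in separate cultures would test.

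Ribosomal protein mRNAs were lower, 73 of 77, by a median log2 fold change of −0.34, while 20 of 33 ribosome biogenesis genes were higher. After a correction of the length trend the median was −0.29 and 70 of 77 were still called lower. Lengths were those of each gene's longest annotated transcript, which need not be the one sequenced. The correction may therefore fall short, and a transcript length bias is not ruled out. After a correction of the GC trend the median was −0.35. Reads assigned to pseudogenes instead were argued against by the sum over the 77 genes and 1541 pseudogene rows, which fell by 0.39 on the log2 scale, with replicates at most 0.0234 apart. A lower share of ribosomal protein mRNA may be biological, as a hypothesis found and tested on the same data. INO80 loss, the interferon response, the siRNA itself and a difference between cultures remain open as its source.

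FN1, TAGLN, TGFB2 and MYL9, 4 contractile or matrix genes singled out after their values were seen, were higher, while the lists of matrix genes (camera adjusted p = 0.0667) and smooth muscle markers (0.394) were not called and POSTN, THBS1 and RGS5 fell. For FN1, which gained 6074 CPM, smooth muscle cells as the source were argued against by the 13 other markers of those cells and pericytes. Their median was 0.115 CPM in siINO80 cells and 0.0807 CPM in control cells, and ACTA2 was at 5.17 ± 0.159 against 5.54 ± 0.0384 CPM. However, SMTN rose from 249.6 ± 2.56 to 302 ± 1.55 CPM, and CNN1 rose on 11 and 12 counts against 3 and 1. A small share of smooth muscle cells could leave the median this low, so it does not decide for TAGLN, TGFB2 and MYL9. Fibroblasts were argued against for FN1 by the sum of all 14 fibroblast markers. That sum gained 6.19 CPM, from 23.9 ± 1.24 to 30.1 ± 0.122. TAGLN gained 73.2 CPM and TGFB2 rose from 15.7 to 69.2 CPM, beside which the gain of the sum is not small enough to decide. The sum was not set against MYL9. COL1A1 and COL3A1 fell and COL1A2 rose from 15.3 ± 1.15 to 27.6 ± 0.445 CPM. GC content bias was argued against by the GC correction, after which the smallest log2 fold change of the 4 genes was 1.26. INO80 loss, the siRNA reagent and a difference between cultures remain open as the source of the rise of these 4 genes. So do smooth muscle cells and fibroblasts for TAGLN, TGFB2 and MYL9.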
